A study of Homo sapiens with 10 samples.

How the data were processed

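Gene expression was measured by RNA sequencing in 10 libraries of T-HESCs, 5 after siRNA against SCGB2A1 and 5 after control siRNA, grouped and numbered by their titles. Per the submitters' processing notes, the tools were fastp, HISAT2 and RSEM, with no version or role, and the build was GRCh38.p14. The library kit, strandedness and read length are not given in the sources used here, since the labels' protocol is a placeholder. Without strand, reads of overlapping and antisense genes cannot be told apart. The labels give the molecule as total RNA and name no selection of poly(A) RNA.

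The deposited count table gives whole-number counts per gene symbol. If RSEM made them they are estimated counts that the authors rounded, and no source says so. The deposited TPM values sum to between 999949 and 999999 per library and follow the counts within each library, with an SD of log2(TPM / count) of at most 0.00707 after centring. The deposited FPKM values keep the depth of the library and are not a fixed multiple of the counts: the same SD was 0.335 to 0.342, over 6859 genes with at least 20 counts in every library. The authors' normalized counts are on a log2 scale and go below 0, as a shrunken log transform gives, and they were used as they are. A planned log2(value + 1) of that table was therefore not run. Of the 24225 rows, 2110 are second copies of a symbol, named with a suffix, of which 719 were tested. Among 14309 rows with at least 50 counts, 756 have the same counts as another row, so reads of near-identical copies are uncertain.

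Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults left 12247 genes, libraries were scaled by TMM, and a quasi-likelihood fit (glmQLFit, glmQLFTest) with the group as the only term gave log2 fold changes, written as SCGB2A1 siRNA minus control siRNA, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. SE is the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to 1 CPM per 1e6 counts of the TMM-scaled library, and log2 CPM used a prior count of 2. For a gene at 0 counts in a group, the fold is a bound against 3 counts over the group. Floors and intervals cover counting error only, since the reads carry no stated molecular identifiers. Single measures of the libraries were compared by exact two-sided permutation tests over 252 arrangements in scipy 1.17.1, where p cannot go below 0.00794.

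Before the data were examined, 28 gene lists with 965 symbols were fixed, of which 888 symbols matched a row through RefSeq names of the same build (98.4% of rows matched a RefSeq symbol). The 27 lists with at least 3 tested members were tested by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with an estimated correlation and by fry. The lists covered secretoglobins, cell cycle (3 lists), decidualization, stromal identity, p53, interferon, stress, cholesterol, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, histones, matrix, contractile genes, TGF-beta, inflammation, immediate early genes, Wnt, apoptosis, autophagy, small RNA pathway, epithelial, endothelial and leukocyte markers, and housekeeping genes. The rule for named genes, also fixed then, took SCGB2A1 and CDK3, up to 10 genes per direction with the largest changes among those past the threshold with a mean of at least 1 CPM, up to 4 members past the threshold of each called list, and PRL, IGFBP1, FOXO1, HAND2, MKI67, CCND1 and CDKN1A. No gene passed, so the parts on genes and members past the threshold named none. All other genes in the text were chosen after their values were seen.

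Replicates were compared before averaging. The chi-square per degree of freedom between libraries of a group was 8.58 to 60.8, so no pair agreed within sampling noise. The labels give no batch, date or lane. Principal component 1 of the log2 CPM values held 22.7% of the variance and component 2 held 16.5%. Dispersion corresponded to a biological coefficient of variation of 0.317.

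The edgeR and camera steps were tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed by known folds. Of 50 genes at each size, edgeR recovered 2% at 1.5-fold, 26% at 2-fold and 82% at both 4-fold and 8-fold, and called 6 of 11635 unchanged genes. Genes that the count filter removed count as missed here. Of those tested, 41 of 45 were recovered at 4-fold and 41 of 41 at 8-fold. A list shifted 1.5-fold was called, and 0 of the 26 other lists were. The simulated genes were drawn independently of each other, so this does not cover false calls where the genes of a list move together. Nor does it cover shifts that many genes of a library share. In the lists that camera called in these data, the estimated correlation ran from 0.11 to 0.41.

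Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2 size factors and upper quartile scaling in edgeR, no filter on low counts, a filter of 1 CPM in 5 libraries, robust dispersions, the replicate number as a block, a 2-fold threshold, limma on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1), and each library left out. Added after seeing the data were fits without both libraries numbered 1, without second copies of a symbol, with offsets per library for GC content and transcript length (GENCODE release 29, 90.0% of tested genes), and limma on the deposited log2 values. Splits of the libraries into other groups of 5 were drawn 100 times of 126 possible, the real one included. Figures were drawn with matplotlib 3.10.9.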

Results

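RNA was sequenced from T-HESCs, a line of immortalized human endometrial stromal cells, after transfection with an siRNA against SCGB2A1 or with a control siRNA. SCGB2A1 encodes a small secreted protein of the secretoglobin family. Each group held 5 libraries, 10 in all. The title of the series names SCGB2A1, the cyclin-dependent kinase CDK3, proliferation and decidualization, the conversion of endometrial stromal cells into secretory cells that prepares the uterus for implantation. The single comparison of the design was therefore SCGB2A1 siRNA against control siRNA, read first at SCGB2A1 and CDK3 and then at genes of the cell cycle and of decidualization. The deposited count table held 24225 rows, and total counts ran from 1994676 to 4193011 per library. The mean total was 3407097 ± 530637 (SD, n = 5) after SCGB2A1 siRNA and 2661210 ± 712705 (SD, n = 5) in the controls. The labels do not say whether the 5 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

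SCGB2A1 (chromosome 11, 62208673 to 62213943, GRCh38.p14) was present in every control library and had 0 counts in all 5 libraries after SCGB2A1 siRNA. Its mean control level was 1013 ± 1541 CPM (count scaled to library size, SD, n = 5). The 5 siSCGB2A1 libraries together held 17035486 counts. On their TMM-scaled library sizes, 0 counts allow a level of up to 0.184 CPM (3 counts over the group, counting error only). Against that floor SCGB2A1 was at least 5518-fold lower than the control mean, a log2 change of -12.43 or beyond, and at least 691-fold lower than the lowest control library. The tables hold no reads, so where the control reads lie along the gene, on which these bounds rest, was not checked. In an exact two-sided permutation test of the CPM, p was 0.00794, the smallest that 252 arrangements of the libraries can give (adjusted p = 0.0238 over 3 such tests). The control libraries were far apart. Control replicate 1 had 7930 counts (3700 CPM), replicate 5 had 3375 (945 CPM), and replicates 2, 3 and 4 had 349, 395 and 354 (127, 162 and 135 CPM), a 29.2-fold range. With that spread the adjusted p of edgeR's quasi-likelihood test was 0.194. Without control replicate 1 the bound was a log2 change of -10.86 and the adjusted p was 0.0315. The Wald test of DESeq2 gave an adjusted p of 9.14e-13, and over 25 alternatives the adjusted p ran from that value to 0.796 in limma-voom. Of the 11 secretoglobins on a list fixed in advance, SCGB2A1 was the one with a row in the table, so that the list could not be tested as a set. Its member count past the threshold was 0 over all genes tested and 1 adjusted over the list alone.

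**Figure D1:**
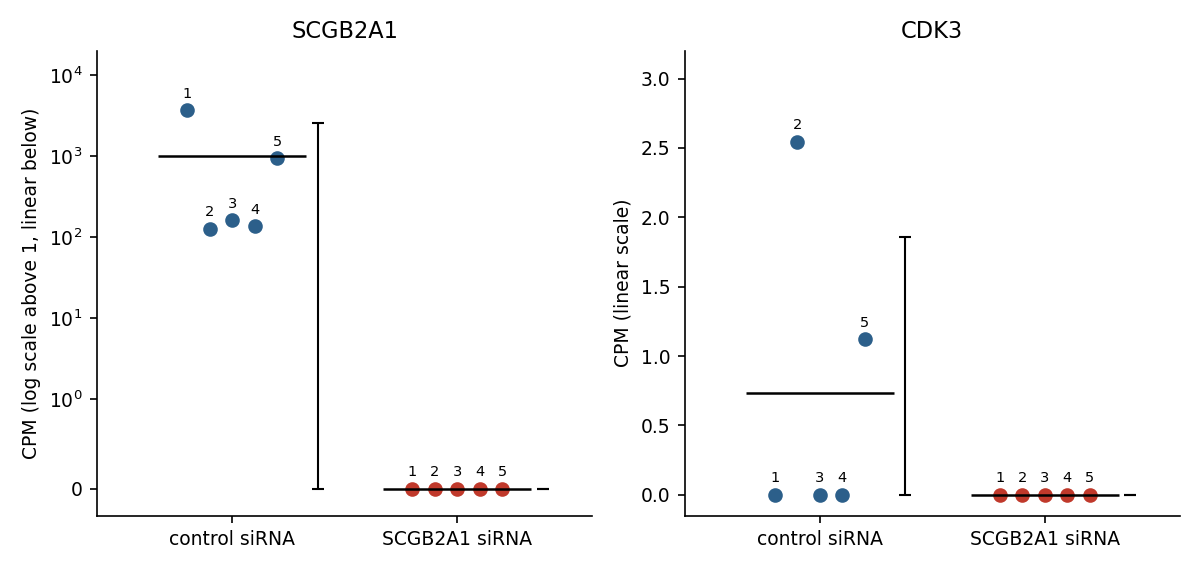
CPM of SCGB2A1 (left, log scale above 1) and CDK3 (right, linear scale) in each library, control siRNA in blue and SCGB2A1 siRNA in red; points carry their replicate number, horizontal lines are group means and the bars beside them show 1 SD, drawn no lower than 0. SCGB2A1 lies between 127 and 3700 CPM in the controls and at 0 in the 5 libraries with SCGB2A1 siRNA, and CDK3 lies at 0 in all but 2 control libraries.

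CDK3, a kinase that acts at the exit from quiescence, was close to undetected in both groups at this depth. The gene (chromosome 17, 76000855 to 76005998) had 0 counts in the 5 siSCGB2A1 libraries and 11 counts in the controls, 7 in replicate 2, 4 in replicate 5 and 0 in the other 3. The control mean was 0.733 ± 1.12 CPM (SD, n = 5), and the floor of 3 counts over the siSCGB2A1 group placed the level after SCGB2A1 siRNA at least 3.99-fold below that mean, a log2 change of -1.997 or beyond. Without control replicate 2 that bound was -0.62. The exact two-sided permutation test did not separate the groups (p = 0.444, adjusted p = 0.667 over 3 tests). CDK3 fell below the count filter of edgeR and has no adjusted p. The readthrough gene TEN1-CDK3 (chromosome 17, 75979217 to 76005999) overlaps CDK3 and can share its reads. It stood at 5.92 ± 3.94 CPM after SCGB2A1 siRNA and 5.55 ± 2.45 CPM in the controls (SD, n = 5 each; log2 fold change 0.14, SE 0.50, edgeR adjusted p = 0.977). The sum of CDK3 and TEN1-CDK3 was 5.92 ± 3.94 against 6.29 ± 2.29 CPM (SD, n = 5 each), also without a difference in the exact permutation test (p = 0.849, adjusted p = 0.849).

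Among genes of the cell cycle, none of the tested members passed the threshold in edgeR, over all genes or adjusted over the list alone. MKI67, the gene of the proliferation antigen Ki-67, stood at 62.7 ± 14.9 CPM after SCGB2A1 siRNA and 62.8 ± 22.3 CPM in the controls (SD, n = 5 each; log2 fold change -0.01, SE 0.25). CCND1, which encodes cyclin D1, stood at 417 ± 98.2 against 369.6 ± 126.6 CPM, and CDKN1A, which encodes the inhibitor p21, at 576 ± 99.6 against 534 ± 78.4 CPM. Their adjusted p in edgeR ranged from 0.930 to 0.995. The list of cyclin-dependent kinases, cyclins and inhibitors had 12 of 25 tested members above 0 and 13 below, with a mean log2 fold change of -0.13 (camera adjusted p = 0.711), which ran from -0.20 to -0.04 with each library left out in turn. Its lowest p belonged to E2F3 and CDK1, a transcription factor of S phase entry and the kinase of mitotic entry. CDK1 stood at 7.20 ± 3.75 against 12.97 ± 3.81 CPM (log2 fold change -0.85, SE 0.36, edgeR adjusted p = 0.761). Of 41 S phase and DNA replication genes 29 had a negative log2 fold change (mean -0.07, camera adjusted p = 0.480), with MCM4 of the replicative helicase at 68.5 ± 5.84 against 85.6 ± 11.2 CPM (edgeR adjusted p = 0.765). Of 55 G2/M and mitosis genes 37 did (mean -0.13, camera adjusted p = 0.237), with DLGAP5, a spindle protein, at 4.73 ± 2.13 against 9.14 ± 4.49 CPM (edgeR adjusted p = 0.739). The G2/M list depended on single libraries: camera called it lower without control replicate 1 (mean -0.21, adjusted p = 0.00484) and without siSCGB2A1 replicate 5 (mean -0.20, adjusted p = 0.0324); over 19 alternatives its adjusted p ran from 0.00484 to 0.977. The S phase list was called lower without siSCGB2A1 replicate 5 (mean -0.22, adjusted p = 0.0168) and had a mean of 0.02 without siSCGB2A1 replicate 1, with adjusted p from 0.0168 to 0.956 over the alternatives. With an estimated correlation the adjusted p of each of these 2 lists was 0.893.

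List members named as examples from here on, and in the cell cycle lists above, were chosen after their values were seen. Genes of decidualization were measured without a decidualizing stimulus named in the labels. PRL, the marker hormone of decidual cells, had 1 count over all 10 libraries, and no row of the table used here carries IGFBP1. FOXO1, a transcription factor of the decidual programme, stood at 15.1 ± 5.98 CPM after SCGB2A1 siRNA and 16.4 ± 8.19 CPM in the controls (SD, n = 5 each; edgeR adjusted p = 0.970). HAND2, a progesterone-dependent transcription factor of the stroma, stood at 17.3 ± 6.84 against 17.5 ± 8.09 CPM (edgeR adjusted p = 0.992). Of 54 decidualization genes 34 were tested, 10 with a positive and 24 with a negative log2 fold change. The mean was -0.13 (camera adjusted p = 0.237), and it ran from -0.20 without siSCGB2A1 replicate 1 to -0.05 without control replicate 1. In this list 0 members passed in edgeR over all genes or adjusted over the list alone. STAT3, which carries the signal of LIF and IL-11, stood at 52.5 ± 15.3 against 77.0 ± 10.5 CPM (log2 fold change -0.55, SE 0.21, edgeR adjusted p = 0.739). HOXA10, a patterning gene of the uterus, stood at 17.6 ± 4.497 against 24.2 ± 5.64 CPM (log2 fold change -0.46, SE 0.23, edgeR adjusted p = 0.776). Stromal identity genes had a mean log2 fold change of -0.10 over 25 tested members (camera adjusted p = 0.480), among them MME, the stromal surface peptidase CD10, at 33.4 ± 5.19 against 52.8 ± 17.1 CPM (edgeR adjusted p = 0.739).

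Over the 12247 genes tested, 0 were higher and 0 lower after SCGB2A1 siRNA at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 784 genes, 419 higher and 365 lower, where 612 are expected with no change. limma-voom also called 0 genes. Some alternatives called 1 gene lower, SCGB2A1, among them the fits without a filter on low counts or without control replicate 1 and limma on the TPM, FPKM or deposited log2 values. DESeq2 called 1 gene higher and 3 lower, and these 4 were SCGB2A1, the lncRNA NEAT1 and the rows HCG15_1 and LY6G5B_1, both second copies of a symbol. The median SE of a log2 fold change was 0.28. Counts were also simulated from the means and dispersions of these libraries, each gene drawn independently. There edgeR recovered 2% of genes changed 1.5-fold, 26% of those changed 2-fold and 82% of those changed 4-fold, out of 50 genes at each size. Shifts that many genes of a library share were not simulated, so recovery in the real libraries may differ. At 4-fold the count filter left 45 of the 50, and 41 of these were recovered.

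After SCGB2A1 the next smallest adjusted p in edgeR was 0.739. The genes named in this and the next paragraph were chosen by their unadjusted p after the values were seen, as the 10 with the smallest p in each direction among protein-coding genes with a single row in the table and a mean of at least 1 CPM. On the higher side, CAMTA2, a calmodulin-binding transcription activator, stood at 14.5 ± 4.80 against 5.30 ± 1.61 CPM (SD, n = 5 each; log2 fold change 1.43, SE 0.32). GTF2I, a transcription factor, stood at 10.1 ± 4.49 against 2.96 ± 1.57 CPM (1.72, SE 0.43), though this gene has near-identical pseudogenes that can share its reads. TGFBR3L stood at 11.2 ± 1.66 against 5.39 ± 0.967 CPM and DNM2, which encodes the membrane-cutting GTPase dynamin 2, at 22.1 ± 3.65 against 12.9 ± 1.70 CPM. EIF3C, a subunit of translation initiation factor eIF3 with a near-identical paralog, stood at 143 ± 22.4 against 99.0 ± 5.51 CPM. KIFC3, a kinesin motor, ARMC6, PLXNB2, a semaphorin receptor, and the histone genes H2AC17 and H4C3 completed the 10, with log2 fold changes from 0.72 to 2.25.

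On the lower side, COX7A2, a subunit of cytochrome c oxidase, stood at 2.66 ± 0.891 against 9.42 ± 3.35 CPM (SD, n = 5 each; log2 fold change -1.81, SE 0.39), and LEPR, the leptin receptor, at 6.90 ± 3.04 against 22.02 ± 8.69 CPM (-1.64, SE 0.35). TPH1, the tryptophan hydroxylase of serotonin synthesis, stood at 20.3 ± 3.195 against 36.0 ± 5.45 CPM, and PIWIL1, a Piwi protein of the germ line, at 25.2 ± 8.22 against 51.6 ± 15.7 CPM. COPS2, a subunit of the COP9 signalosome, stood at 6.14 ± 1.99 against 14.5 ± 3.35 CPM. EIF5AL1, a close copy of EIF5A that can share its reads, stood at 148 ± 58.8 against 325 ± 52.1 CPM. ANKS1B, CFDP1, KIAA1549 and SLC4A1, the red cell anion exchanger, had log2 fold changes from -0.98 to -0.74. All siSCGB2A1 libraries lay above all controls for 6 of the 10 higher genes, and below all controls for 8 of the 10 lower genes. Over all tested genes the groups did not overlap for 65 on the higher and 78 on the lower side, where chance gives 97.2 in total (0.794%).

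**Figure D2:**
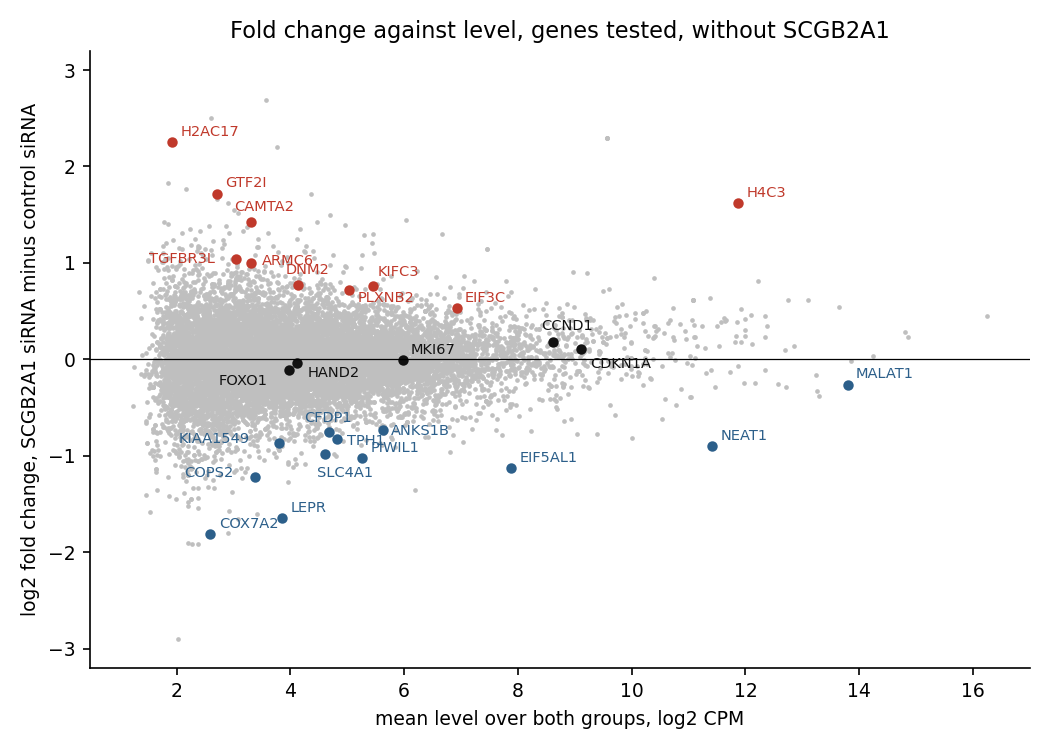
Log2 fold change (SCGB2A1 siRNA minus control siRNA) against mean level in log2 CPM for the genes tested in edgeR, 1 grey point per gene, without SCGB2A1, which has 0 counts in 1 group. Black points are genes named in advance, red and blue points are the higher and lower genes named after their values were seen together with NEAT1 and MALAT1; no gene shown passed an adjusted p of 0.05 in edgeR, and NEAT1 lies at -0.90.

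The lncRNA NEAT1, the scaffold of nuclear paraspeckles (chromosome 11, 65422798 to 65445540), stood at 1910 ± 491 CPM after SCGB2A1 siRNA and 3567 ± 622 CPM in the controls (SD, n = 5 each; log2 fold change -0.90, SE 0.21). Its level was lower in 5 of 5 siSCGB2A1 libraries than in every control. The adjusted p was 0.739 in edgeR and 0.0473 in DESeq2, and it ran from the latter to 0.9996 over 25 alternatives. MALAT1, the neighbouring nuclear lncRNA, stood at 12935 ± 3024 against 15518 ± 1574 CPM (log2 fold change -0.26, SE 0.19, edgeR adjusted p = 0.838). Both were named after their values were seen. All lncRNAs together took 4.77 ± 0.241% of the counts after SCGB2A1 siRNA and 5.52 ± 0.636% in the controls (SD, n = 5 each), with p = 0.0397 in an exact two-sided permutation test and an adjusted p of 0.105 over 11 library measures.

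Of the 28 fixed lists, 27 had at least 3 tested members, and 4 of these passed an adjusted p of 0.05 in camera with a preset inter-gene correlation of 0.01. With an estimated correlation 0 lists passed, and fry called 0 lists (adjusted p = 0.878 for each). No member of the 4 passed in edgeR over all genes tested. Cytosolic ribosomal proteins rose by camera, with a mean log2 fold change of 0.11 over 73 members, 46 of them positive (adjusted p = 0.00283; adjusted p = 0.893 with an estimated correlation). RPS9, of the small subunit, stood at 103 ± 14.5 against 70.6 ± 11.3 CPM and RPL28, of the large subunit, at 6087 ± 2693 against 3473 ± 1063 CPM (SD, n = 5 each). No member passed adjusted over the list alone. The call held without any 1 of the 10 libraries, though the mean was 0.06 without siSCGB2A1 replicate 2, 4 or 5, 0.17 without siSCGB2A1 replicate 3 and 0.18 without control replicate 5. By share, ribosomal protein mRNAs took 12.9 ± 1.38% of all counts against 11.7 ± 1.37% (exact permutation p = 0.206, adjusted p = 0.284).

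Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, rose by camera with a mean log2 fold change of 0.93 over 9 tested members of 49, 8 of them positive (adjusted p = 0.00319; adjusted p = 0.893 with an estimated correlation). H2AC17 (2.25, SE 0.64) and H4C3 (1.62, SE 0.47) passed adjusted over the list alone, with an adjusted p of 0.0165 each. The log2 fold change of H4C3 was 0.88 without siSCGB2A1 replicate 2, and that of H2AC17 was 3.002 without control replicate 4. H4C3 stood at 5661 ± 5291 against 1839 ± 619 CPM (SD, n = 5 each), and siSCGB2A1 replicate 2 alone reached 14726 CPM. Without that library the list had a mean of 0.46 and an adjusted p of 0.0997. The same library held the highest share of 18S ribosomal RNA, which likewise lacks a poly(A) tail: the share was 0.450 ± 0.566% after SCGB2A1 siRNA against 0.108 ± 0.057% (exact permutation p = 0.0635, adjusted p = 0.116). Copies of a histone gene can share reads, so single members are uncertain.

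Mitochondrially encoded genes fell by camera, with a mean log2 fold change of -0.22 over 13 members, 11 of them negative (adjusted p = 0.00788; adjusted p = 0.893 with an estimated correlation). ND3, of complex I, stood at 497 ± 175 against 849 ± 373 CPM, and ATP8, of the ATP synthase, at 127 ± 28.2 against 187 ± 43.3 CPM (SD, n = 5 each). The 13 genes took 3.32 ± 0.628% of the counts after SCGB2A1 siRNA and 4.24 ± 0.430% in the controls (exact permutation p = 0.0318, adjusted p = 0.105). The call was lost without siSCGB2A1 replicate 1, siSCGB2A1 replicate 3 or control replicate 2 (adjusted p = 0.0751, 0.0956 and 0.0662, with means of -0.14, -0.15 and -0.14), and without siSCGB2A1 replicate 2 the mean was -0.37. It was also lost without both libraries numbered 1 (mean -0.16, adjusted p = 0.109), where the other 3 lists were still called. Interferon-stimulated genes also fell by camera, with a mean of -0.21 over 38 members, 29 of them negative (adjusted p = 0.0132; adjusted p = 0.893 with an estimated correlation). IFIT3, an antiviral effector, stood at 747 ± 291 against 1313 ± 448 CPM, and STAT1, the transcription factor of the interferon response, at 34.6 ± 6.06 against 47.4 ± 9.93 CPM. No member of either list passed adjusted over the list alone. The call for the interferon-stimulated genes was lost without siSCGB2A1 replicate 1, control replicate 3 or control replicate 4 (adjusted p = 0.0639, 0.206 and 0.120, with means of -0.17, -0.12 and -0.18).

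**Figure D3:**
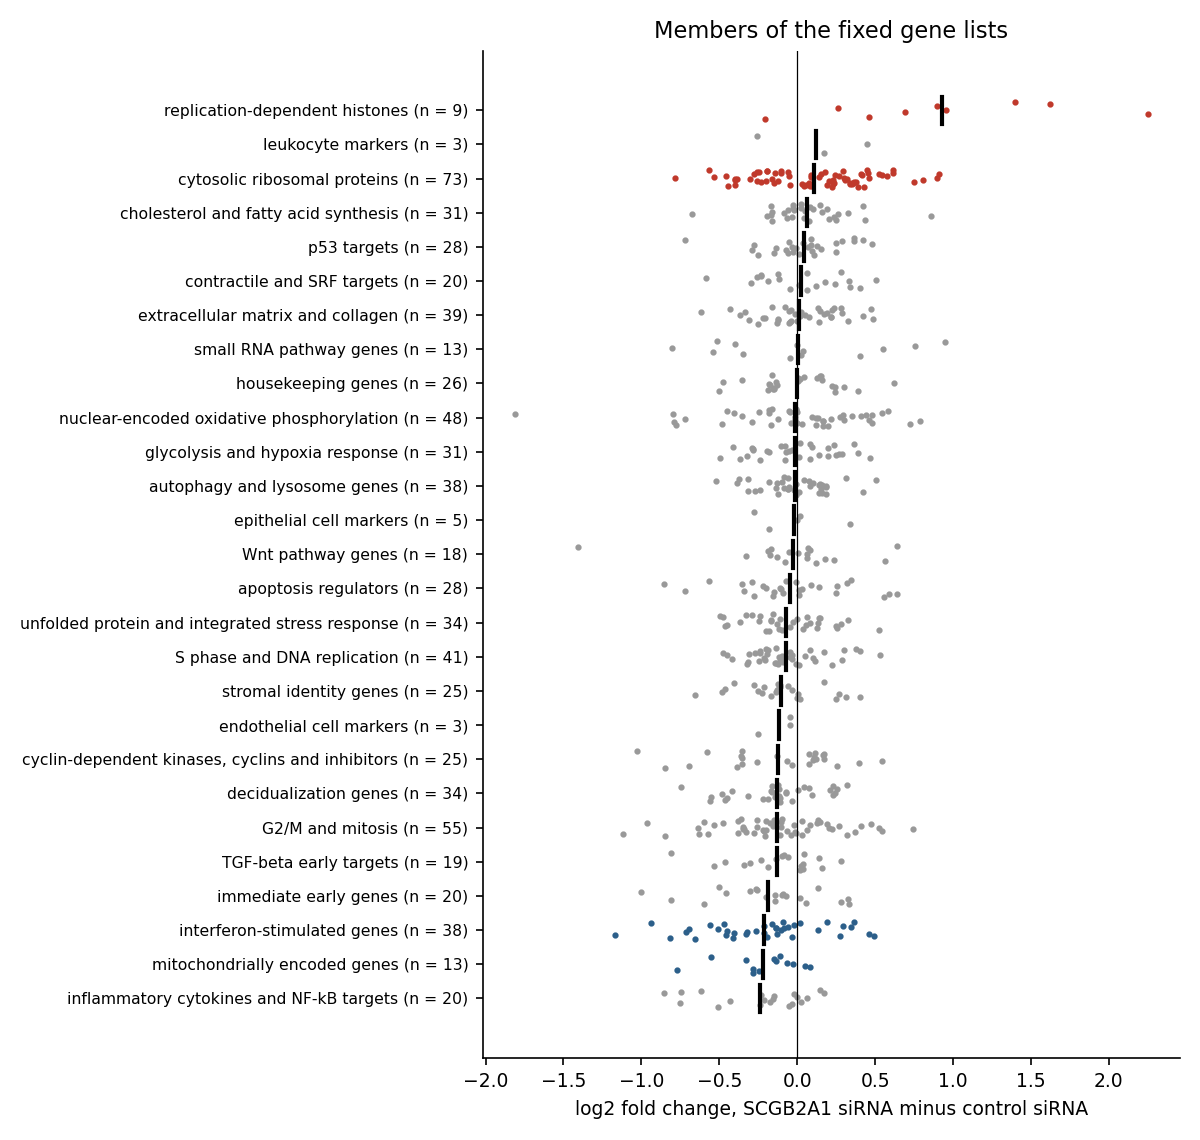
Log2 fold change (SCGB2A1 siRNA minus control siRNA) of each tested member of the 27 fixed lists, 1 point per gene, with the mean of each list as a black bar and the number of tested members in brackets. Lists in red or blue passed camera with the preset correlation, histones at 0.93 and ribosomal proteins at 0.11 on the higher side and mitochondrially encoded genes at -0.22 and interferon-stimulated genes at -0.21 on the lower side; none passed with an estimated correlation.

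The other lists did not pass in camera, and except for COX7A2 in oxidative phosphorylation (adjusted p = 0.0165) none of their members passed adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes had a mean log2 fold change of -0.01 over 48 members (camera adjusted p = 0.484), with 23 positive and 25 negative. NDUFA13, of complex I, stood at 964 ± 292 against 583 ± 126 CPM and COX6C, of complex IV, at 7.54 ± 2.08 against 13.1 ± 4.41 CPM (SD, n = 5 each). Immediate early genes had a mean of -0.19 (20 members, 0.514), TGF-beta early targets -0.13 (19 members, 0.489) and the unfolded protein and integrated stress response -0.07 (34 members, 0.702). p53 targets had a mean of 0.04 (28 members, 0.702), apoptosis regulators -0.05 (28 members, 0.929), autophagy and lysosome genes -0.01 (38 members, 0.781) and Wnt pathway genes -0.03 (18 members, 0.784). Cholesterol and fatty acid synthesis had a mean of 0.07 (31 members, 0.480), glycolysis and hypoxia response -0.01 (31 members, 0.711), extracellular matrix and collagen 0.01 (39 members, 0.729) and contractile and SRF targets 0.02 (20 members, 0.711). Camera's direction was up where the mean was negative for glycolysis, oxidative phosphorylation, Wnt and housekeeping genes, and down where the mean was positive for small RNA pathway genes; the median of the Wnt list was 0.03. Without control replicate 5 camera called cholesterol and fatty acid synthesis higher (mean 0.22, adjusted p = 0.00789), and without siSCGB2A1 replicate 5 its mean was -0.08; over all libraries its adjusted p was 0.893 with an estimated correlation. Small RNA pathway genes, which load and use siRNAs, had a mean of 0.00 over 13 members (camera adjusted p = 0.781), 7 positive and 6 negative. Of the 13, 5 had an unadjusted p under 0.05 in edgeR. So had 9 of the 48 oxidative phosphorylation genes and 784 of all 12247 genes tested. Camera tests a shared direction, so these means do not show members that move both ways. TARBP2 stood at 19.1 ± 4.85 against 11.2 ± 4.10 CPM and DICER1 at 9.25 ± 1.55 against 13.5 ± 2.79 CPM. Housekeeping genes had a mean of 0.00 over 26 members (camera adjusted p = 0.711).

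Some markers of other cell types were present in every library of both groups. KRT18 and KRT8, keratins of simple epithelia, ranged from 62.8 to 131.7 and from 12.7 to 38.7 CPM, the leukocyte markers LYZ and LCP1 from 20.9 to 58.2 and from 18.5 to 56.5 CPM, and the endothelial receptor TIE1 from 17.6 to 44.4 CPM. Of the same lists, FLT1 (6.89 to 26.1 CPM), CD68 (11.5 to 35.2 CPM) and TEK (2.33 to 7.44 CPM) were also present in every library. So were the epithelial marker GRHL2 (9.80 to 36.7 CPM) and, at lower levels, the epithelial markers KRT7, MUC1, PAX8 and SPINT1. Other members were close to undetected: PECAM1, VWF, CDH5, KDR and CD74 had at most 2 counts in any library, and LAPTM5 and FCER1G at most 3. These levels therefore do not show that endothelial cells or leukocytes were in the cultures. EPCAM and KRT19 had 1 count together in the control libraries. A stromal line can also express KRT8 and KRT18, and the source of GRHL2 was not tested. The 5 tested epithelial members had a mean log2 fold change of -0.02 (camera adjusted p = 0.954). Endothelial markers had a mean of -0.12 over 3 members (adjusted p = 0.711) and leukocyte markers 0.12 over 3 members (adjusted p = 0.711).

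Some inflammatory genes stood apart in the 2 libraries numbered 1, 1 in each group. The list of inflammatory cytokines and NF-kB targets had a mean log2 fold change of -0.24 over 20 members, 4 positive and 16 negative (camera adjusted p = 0.480), and no member passed in edgeR over all genes or adjusted over the list alone. IL1B, the cytokine interleukin-1 beta, stood at 580.0 CPM in siSCGB2A1 replicate 1 and 517 CPM in control replicate 1, and between 8.36 and 102.8 CPM in the other 8 libraries. CXCL8, which encodes interleukin-8, stood at 1778 and 1328 CPM there against 72.0 to 434 CPM in the other 8, and INHBA, the activin A subunit, at 1354 and 1247.5 CPM against 130.1 to 207 CPM. IL11, SERPINB2, STC1 and DKK1 had means in these 2 libraries of 11.5, 14.8, 4.14 and 2.92 times the median of the other 8. PTGS2, another member of the list, did not stand apart, at 3.31 and 4.67 CPM against 0 to 5.32 CPM in the other 8. The mean centred log2 CPM of the list was 0.91 in siSCGB2A1 replicate 1 and 1.03 in control replicate 1, the highest of their groups. It also reached 0.55 and 0.37 in control replicates 3 and 4. All genes of this paragraph were chosen after their values were seen. The list's value moved with single libraries: camera called it lower without siSCGB2A1 replicate 1 (mean -0.71, adjusted p = 0.00645), without control replicate 2 (-0.37, 0.0392) and without control replicate 5 (-0.37, 0.0159). Its mean was 0.08 without control replicate 1, -0.06 without siSCGB2A1 replicate 2 and -0.09 without siSCGB2A1 replicate 5. Without both libraries numbered 1 it was -0.36 (adjusted p = 0.324). Over all libraries its adjusted p was 0.893 with an estimated correlation. Without siSCGB2A1 replicate 1 camera also called lower the immediate early genes (-0.41, 0.0190), TGF-beta early targets (-0.31, 0.0394) and the unfolded protein and integrated stress response (-0.23, 0.0274), each at an adjusted p of 0.893 over all libraries with an estimated correlation. Without control replicate 1 the means of these 3 lists were 0.08, 0.08 and 0.09.

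**Figure D4:**
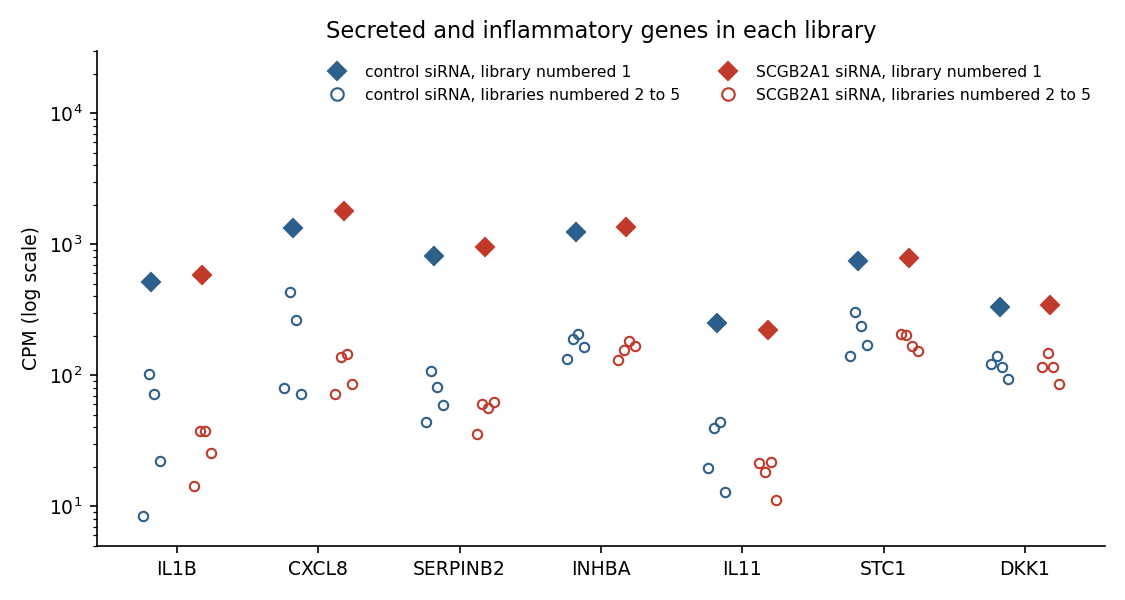
CPM on a log axis of IL1B, CXCL8, SERPINB2, INHBA, IL11, STC1 and DKK1 in each of the 10 libraries, control siRNA in blue and SCGB2A1 siRNA in red, with diamonds for the libraries numbered 1 and circles for the other 8. The 2 diamonds lie above all circles for each of the 7 genes, at 580.0 and 517 CPM for IL1B against at most 102.8 CPM.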

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

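The tests of epithelial cells and knockdown for SCGB2A1, of GC content and length for the lists, and all tests on the libraries numbered 1 were chosen after the results were seen; the tests of depth and of other splits were planned. The tests of epithelial cells and leukocytes, with their limit of 5 CPM and margin of 10 times, are the third form tried, set with all values in view. A library is given here where its gap to the nearest other library of its group exceeded 0.71 of the group's range, Dixon's 95% value for 5 libraries. This held in 26 of 104 groups tested, where chance gives 5.2. Many of these genes were picked because they stood apart, so the excess is no test of them.

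SCGB2A1 stood at 3700 CPM in control replicate 1 and between 127 and 945 CPM in the other controls, and at 0 counts in all siSCGB2A1 libraries. Knockdown by the siRNA may account for the difference (exact permutation p = 0.00794, the smallest possible), but so would anything else that follows the groups, and 0 counts in all 5 libraries is unusually complete for an siRNA. The tables argue against epithelial cells in the control cultures, unless these carry many times more SCGB2A1 than markers. The 11 epithelial markers under 5 CPM after SCGB2A1 siRNA summed to 18.8 ± 3.97 CPM in the controls and 19.0 ± 4.58 after SCGB2A1 siRNA (SD, n = 5 each). Of these, ELF3 had 7 counts against 0 and CLDN7 2 against 11. The mean excess of SCGB2A1 was 113 times their excess plus 2 SD (30.6 times with all 14 markers). Control replicate 1 raises that mean, so the ratio is much lower for control replicates 2, 3 and 4, at 127, 162 and 135 CPM. Of 1122 other genes at 100 CPM or more in the controls, the lowest, HAS2-AS1, was at 38.4% of its control level. Where the SCGB2A1 reads of the controls map, whether they came from their own cells, whether a library was mislabelled, and what spread the level 29.2-fold were not tested.

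In the libraries numbered 1, siSCGB2A1 replicate 1 and control replicate 1 stood at 580.0 and 517 CPM for IL1B, 1778 and 1328 for CXCL8, 958 and 811 for SERPINB2, 1354 and 1247.5 for INHBA, 219.9 and 252 for IL11, 792 and 743 for STC1, and 341 and 332 for DKK1. IL6 stood at 156 CPM in both, where the other siSCGB2A1 libraries ranged from 19.1 to 51.7 CPM and the other controls from 29.8 to 117.5 CPM. Read in the same way, the low markers argue against leukocytes unless these carry over 100 times more IL1B than such markers. The 8 leukocyte markers under 5 CPM in the other 8 libraries, CD74, CD14 and CORO1A among them, summed to 4.96 and 3.27 CPM here and 3.66 ± 2.04 (SD) there. The excess of IL1B was 112 times theirs plus 2 SD. With all 11 markers it was 9.99 times, just under the margin of 10 times, so that form cannot tell. There CD68, LYZ and LCP1 could hide a small share. A day or culture shared by these libraries may be a candidate source and stays open: the labels give no day, and a number shared by chance has a probability of 0.2 whatever the data, so this was not tested.

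For the 4 gene lists called by camera, 4 of 4 were still called after every library was thinned to 1994676 counts. Thinning keeps the expected share of each gene, so it could move the list means little and does not decide whether depth played a part. With offsets for GC content and length, camera with the preset correlation still called 3 of the 3 lists with GC values. Many other splits of the libraries also gave calls at that threshold, so this does not decide whether GC content and length played a part. The mitochondrially encoded genes had no GC values, so the offsets did not test that list. Chance cannot be excluded: 73 of 100 splits of the 10 libraries, the real one included, gave at least the 4 lists of the real split, and the highest of the others gave 14. For genes at an unadjusted p under 0.05 it cannot be excluded either, with 784 in the real split, at least as many in 20 of 100, and at most 1670 in another. The real split called 0 genes in edgeR at an adjusted p, which all 100 splits match by construction, so that this count says nothing about chance. The highest other, with siSCGB2A1 replicates 1, 2 and 3 and control replicates 2 and 4 on one side, called 40, while the median of the others was 0. On principal component 1 the libraries of that side lay from -61.1 to 0.627 and the rest from -3.18 to 34.2. The 40 genes may point to a structure of the samples that the groups do not fully follow. Its source was not tested.

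Single libraries also stood apart in other measures. PLXNB2 was at 28.2 CPM in siSCGB2A1 replicate 5 (others 42.7 to 44.8), COX7A2 at 3.64 CPM in control replicate 5 (9.83 to 11.8), ANKS1B at 77.2 CPM in control replicate 5 (55.3 to 60.9) and PIWIL1 at 79.3 CPM in control replicate 1 (40.7 to 47.9). MALAT1 was at 18207 CPM in siSCGB2A1 replicate 4 (10524 to 12319) and RNA18SN2 at 4249 CPM in siSCGB2A1 replicate 2 (249 to 829.6). The share of 18S ribosomal RNA was 1.45% in siSCGB2A1 replicate 2 (95% Wilson interval 1.44 to 1.47; others 0.103 to 0.318). The share of MT2A, a metallothionein, was 3.81% in siSCGB2A1 replicate 5 (3.79 to 3.83; others 8.75 to 10.2). The share of ribosomal proteins was 14.1% in control replicate 5 (14.06 to 14.13; others 10.5 to 11.4). The slope of log2 level on GC content was -0.71 per unit of GC in siSCGB2A1 replicate 5 (others 0.62 to 1.09). These intervals cover counting error only.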

How the results depend on the processing

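The GC and length offsets, the deposited log2 values, the fit without second copies of a symbol and the fit without both libraries numbered 1 were chosen after the data were seen. Of the main results over all alternatives 98 were the same, 8 stronger and 11 moved; of those for single genes or lists 877 were the same, 16 weaker, 4 stronger and 27 had the other sign. SCGB2A1 was lower in each alternative. For fits on counts the log2 change given is the bound against 3 counts, which does not depend on the test. It was -12.43 with no filter (edgeR adjusted p = 2.89e-04) and -12.43 with the replicate block (edgeR adjusted p = 2.41e-04). In DESeq2 the bound was -12.44 and the estimate of the tool was -14.12 (Wald test, adjusted p = 9.14e-13). The limma fits gave estimates, not bounds. These were -9.64 on log2(TPM + 1) (limma adjusted p = 2.83e-05) and -12.96 on log2(TPM + 0.1) (2.45e-06). On log2(FPKM + 1) the estimate was -9.82 (6.08e-06), and on the deposited log2 values it was -4.95 (0.00860). Each of these alternatives but DESeq2 called 1 gene lower, SCGB2A1, and 0 higher. DESeq2 called 1 higher and 3 lower. Upper quartile and DESeq2 size factors, robust dispersions, limma-voom, the filter of 1 CPM in 5 libraries (15312 genes tested), GC and length offsets, and the fits without copies or without both libraries numbered 1 called 0 genes, as did the 2-fold threshold, which can only remove calls. The number of lists past the threshold was 0 with an estimated correlation and 0 with fry.

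The sign of small changes turned. CDKN1A was at -0.0044 with GC and length offsets, -0.12 on log2(TPM + 1) and -0.13 on log2(TPM + 0.1). MKI67 was at 0.064 with the offsets, 0.024 in limma-voom, 0.034 with the replicate block and 0.022 on the deposited log2 values. On log2(TPM + 1) and log2(TPM + 0.1) CCND1 was at -0.026 and -0.025 and TEN1-CDK3 at -0.11 and -0.33, and with the replicate block TEN1-CDK3 was at -0.014. On log2(FPKM + 1) FOXO1 was at 0.025 and HAND2 at 0.54. The median of all genes shifted to -0.17 on log2(TPM + 1), -0.23 on log2(TPM + 0.1) and 0.20 on log2(FPKM + 1). Relative to it, CCND1 was at 0.14 and 0.20, CDKN1A at 0.04 and 0.10 and TEN1-CDK3 at 0.05 and -0.11 on the TPM scales, and FOXO1 at -0.18 and HAND2 at 0.34 on the FPKM scale. Otherwise the cause was not tested.

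With each library left out in turn, the bound for SCGB2A1 ran from -12.72 to -10.86 and that for CDK3 from -2.33 to -0.62. Genes lower ran from 0 to 1, genes higher from 0 to 0 and lists past the threshold from 3 to 6. FOXO1 ran from -0.35 to 0.22, HAND2 from -0.21 to 0.21, MKI67 from -0.15 to 0.16, TEN1-CDK3 from -0.22 to 0.39 and the mean of the S phase list from -0.22 to 0.016. The 1 gene lower, SCGB2A1, was called without control replicate 1. The correlation of libraries with the same number, after centring, was 0.204, 0.222, 0.0353, 0.00400 and 0.135 for numbers 1 to 5, and it ran from -0.197 to 0.180 over the 20 pairs with different numbers. Replicates 1 and 2 of siSCGB2A1 correlated best with their own number and replicates 3, 4 and 5 with another. All same-number correlations lay above 0, but they were not tested together against other matchings of the libraries. Whether the numbers pair the libraries therefore stays open. Principal component 2 set siSCGB2A1 replicate 1 and control replicate 1 apart, at 50.7 and 41.4, where each other library lay below 0. The numbers may mark a shared step for some libraries, and neither the main fit nor the splits into other groups used them. The edgeR adjusted p of SCGB2A1 was 0.194 without the block and 2.41e-04 with it. With the replicate block camera, at the preset correlation, also called the inflammatory list lower (-0.25, adjusted p = 0.00546). The estimated correlation was run only on the fit without the block (camera adjusted p = 0.893), so it does not check this call. The planned log2(value + 1) of the deposited normalized counts was not run, since they are logs below 0 in part. CDK3 has no value in the limma fits on TPM, FPKM and log2 values. CDK3, at 11 counts in all, and PRL, at 1, fell below the count filter of the main fit. The reason for their low counts was not tested.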

Other observations

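Other features of these cultures were seen only after the values were examined. MT2A, a metallothionein that binds zinc and copper, took between 3.81% and 10.2% of all counts per library, with 8.40 ± 2.64% after SCGB2A1 siRNA and 6.74 ± 2.23% in the controls (SD, n = 5 each; exact permutation p = 0.302, adjusted p = 0.369 over 11 library measures). The slope of log2 level on GC content was 0.54 ± 0.73 after SCGB2A1 siRNA and -0.54 ± 0.66 in the controls (exact permutation p = 0.0397, adjusted p = 0.105). Across 8367 genes, which are not independent replicates, log2 fold change and GC content had a correlation of 0.27. NEAT1 took 0.183 ± 0.0548% against 0.368 ± 0.0713% of the counts, lower in 5 of 5 siSCGB2A1 libraries than in every control. Its exact permutation p was 0.00794, the smallest possible (adjusted p = 0.0873 over 11 library measures). It was picked from all genes after its values were seen, so neither value is a test of it. The groups did not overlap for 65 tested genes on the higher and 78 on the lower side, where chance gives 97.2 in total. With GC and length offsets the log2 fold change of NEAT1 was -0.79.

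Besides SCGB2A1, 5 rows of the table had 0 counts in all siSCGB2A1 libraries and at least 1 in every control, with at most 5 counts in a library, and 3 had the reverse. TERT, the catalytic subunit of telomerase, had 5 counts over all 10 libraries.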
